A study of Caenorhabditis elegans with 12 samples.

How the data were processed

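Whole Caenorhabditis elegans larvae of 3 genotypes were compared after the same time of feeding: wild type N2 (WT), the caspase mutant ced-3(n717) and the p38 MAP kinase mutant pmk-1(km25). Per the labels' protocols, eggs from bleached adults hatched without food over 24 h. The larvae were then fed OP50 bacteria for 18 h at 20 °C, until nearly all WT worms had reached the third larval stage (L3). Total mRNA and ribosome-protected fragments (RPF, the stretches of mRNA that a ribosome covers) were sequenced from the same worm sample, per the labels. There were 6 worm samples and 12 libraries, which form 6 groups of 2 libraries. The series calls the 2 replicates independent and biological but does not say that they were separate cultures, so every p below measures the spread between these samples.

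The deposited table held whole-number read counts per gene with no normalization, per the file headers and the values themselves. The submitters' processing notes name Bowtie2, STAR and HTSeq with the genome build WBcel235, without their versions or roles. The annotation release, the use of strand, and any filter on read length or on reads with several matches were not stated. Reads shared by near-identical copies (histones, some lectins, collagens and ribosomal protein genes) or by overlapping genes are therefore uncertain for the single gene.

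The table held 46778 genes, of which 46603 were matched by WormBase identifier to the reference annotation of WBcel235 and 43818 to a gene name. Coordinates are those of that annotation. CPM (read counts scaled to a common library size) were computed with TMM-scaled library sizes, and levels are given as mean ± SD over the 2 libraries of a group (n = 2). Total counts were 15471380 to 17150137 per mRNA library and 6708805 to 10115985 per RPF library, and 3 counts in 1 library corresponded to 0.175 to 0.194 CPM in mRNA and 0.297 to 0.447 CPM in RPF. A level of 0 in a group was bounded by 3 counts over the libraries of the group; such bounds cover counting error only.

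Groups were compared with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr with a minimum count of 10 and a minimum total count of 15, robust glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. The 6 mRNA libraries formed 1 fit (13536 genes) and the 6 RPF libraries another (12633 genes). Translation efficiency (TE), the change in RPF beyond the change in mRNA, was the interaction of genotype and assay in a fit of all 12 libraries (13698 genes), which also gave RPF against mRNA in WT. Log2 folds are given ± SE, where the SE was the size of the fold divided by the square root of the test's F statistic. The fits on the real libraries had a biological coefficient of variation of 0.2 in mRNA, 0.23 in RPF and 0.216 in the fit of all libraries.

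Since mRNA and RPF of a replicate came from the same worms, the TE and RPF against mRNA comparisons are also given with the worm sample as a block, called the fit with worm samples paired. The deviations of mRNA and RPF from their group means correlated across genes at 0.20 in WT, 0.69 in ced-3 and 0.74 in pmk-1. This block lowered the coefficient of variation to 0.098.

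Before the data were examined, the following were fixed: the groups, the tests, the alternatives marked as planned, the rule for named genes and 35 gene lists, of which 27 covered pathways and gene families (immunity, stress responses, translation, metabolism, growth and the cuticle) and 8 held markers of tissues and stages. Lists with fewer than 3 tested genes were left out, which left 34. Lists were tested with camera of limma 3.58.1 at its preset correlation between genes of 0.01, again with a correlation estimated from the data, and with fry. Camera sets a list against the other genes and fry tests a list on its own, and their p was adjusted over the lists of the comparison. A list's median is the median log2 fold of its tested genes. The genes of a list were also adjusted over the list alone. Named genes were the 8 with the largest log2 rise and the 8 with the largest fall for a mutant against WT (6 and 6 in other comparisons) among genes past the threshold with a mean of at least 5 CPM and no overlap between the libraries of the groups; ced-3 and pmk-1; up to 4 members past the threshold per list, or the member with the smallest p; and up to 6 genes per direction called in both mutants. Any gene named outside this rule is said to have been chosen after its values were seen.

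Each step was tested on simulated counts drawn from the real means, in which 100 genes changed by each fold. At 4-fold, 79% were recovered for ced-3 against WT in mRNA, 82% for pmk-1 in mRNA, and 74% and 76% in RPF. At 2-fold the shares were 14%, 23%, 13% and 11%. For TE, 41% (ced-3) and 50% (pmk-1) were recovered at 4-fold, and 0% and 4% at 2-fold. With worm samples paired these were 25% and 41% at 4-fold and 0% in both at 2-fold. Simulated libraries were drawn independently, without the deviations that mRNA and RPF of a real worm sample share. The paired simulations therefore do not measure what the paired fit recovers in the real libraries. All genotypes were also simulated with the same spread for a gene, whereas real replicates differed more in the mutants. The SD of the log2 difference between replicates was 0.55 in ced-3, 0.595 in pmk-1 and 0.375 in WT for mRNA. For RPF it was 0.633, 0.592 and 0.462. The shares recovered in simulation therefore need not hold for the real comparisons. Among simulated calls 1.8% to 14.7% were false.

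The alternatives were RLE factors in place of TMM, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, the compared groups alone, protein coding genes alone, glmQLFit without its robust option, and leaving out each library or worm sample in turn. Removing ced-3 replicate 2 and pmk-1 replicate 1 together, splitting the WT libraries between the mutants (in a fit with each WT library as its own group), and treating the paired TE fits as results of their own, were added after the data were seen. Where 1 group keeps a single library, that library is assumed to vary like the other groups. Correlations of folds are across genes, which are not independent replicates. To see what shared WT libraries alone would give, 50 sets of unchanged groups were simulated against them. Principal components were computed from log2 CPM with a prior count of 2. Only vit-1 of the vitellogenins passed the filter, so these were not tested as a list.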

Results

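Counts per gene were measured in WT, ced-3 and pmk-1 worms, with 2 mRNA libraries and 2 RPF libraries per genotype. Total counts ranged from 15471380 to 17150137 in mRNA and from 6708805 to 10115985 in RPF. Protein coding genes held 87.6% to 89.6% of the counts of an mRNA library and 95% to 97.6% of an RPF library. The log2 CPM of replicates correlated across genes at 0.990 in WT, 0.975 in ced-3 and 0.975 in pmk-1 for mRNA, and at 0.982, 0.961 and 0.972 for RPF. Genes that differed by more than 2-fold between replicates numbered 371 in WT, 1135 in ced-3 and 1128 in pmk-1 for mRNA, and 521, 1437 and 1040 for RPF.

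**Figure D1:**
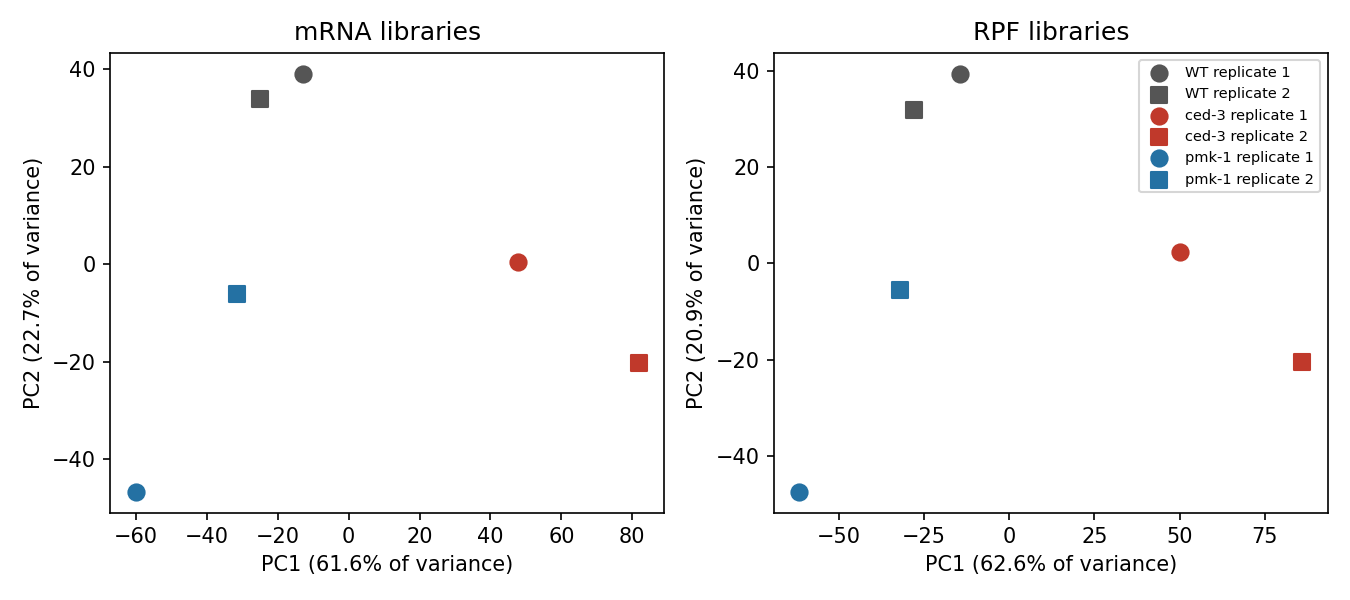
Each point is a library, placed by its scores on the first (x axis) and second (y axis) principal component of log2 CPM, with mRNA and RPF in separate panels, color for genotype and shape for replicate. On the first component, which held 61.6% of the variance in mRNA and 62.6% in RPF, ced-3 replicate 2 (81.8 and 86) and pmk-1 replicate 1 (-60.1 and -61.6) lie farthest apart, and WT lies between the mutants in both panels.

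The mutated genes themselves were read first. The caspase gene ced-3 (WBGene00000417, chromosome IV, 13198261 to 13204137, WBcel235) had 3.66 ± 1.93 CPM in WT mRNA, 5.92 ± 0.704 in ced-3 and 2.43 ± 0.192 in pmk-1, from 36 to 108 counts per library (n = 2 per group). The p38 MAP kinase gene pmk-1 (WBGene00004055, chromosome IV, 8148794 to 8151266) had 36.3 ± 1.12 CPM in WT mRNA, 39.5 ± 2.19 in ced-3 and 35.4 ± 0.146 in pmk-1. In RPF, pmk-1 had 49.8 ± 3.57 CPM in WT, 45.6 ± 4.2 in ced-3 and 25.2 ± 0.27 in pmk-1 worms; its log2 fold in pmk-1 against WT was -0.98 ± 0.15, with an adjusted p of 0.14 by edgeR and 0.0011 by DESeq2. The RPF of pmk-1 were higher in ced-3 than in pmk-1 worms, by 0.85 ± 0.15 on the log2 scale (adjusted p = 0.035). Counts per gene do not separate the part of a gene that an allele changes, so the mRNA levels of both genes did not test the genotype labels.

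The comparison of ced-3 with WT in mRNA asked which transcripts differ without the caspase. In ced-3 worms, some mRNAs of collagens and moulting genes were higher than in WT, though most members of those lists did not pass over all genes. The collagen sqt-1 (WBGene00005016, chromosome II, 11336693 to 11337837) went from 30.1 ± 7.15 to 445 ± 193 CPM, a log2 rise of 3.88 ± 0.38, and the collagen lon-3 rose by 3.65 ± 0.38. The hedgehog-related genes wrt-1 and wrt-2, which are expressed in the epidermis, rose by 3.88 ± 0.31 and 3.87 ± 0.32, and the moulting gene mlt-10 rose by 3.14 ± 0.31. The log2 rise of the collagen sqt-3 was 3.93 with all libraries and 3.28 without ced-3 replicate 2. Worms were taken at 1 feeding time, when nearly all WT worms had reached L3. Larval timing was therefore not separated from genotype for these rises. Some lysozymes rose: lys-7 (chromosome V, 3481432 to 3482600) went from 47 ± 8.76 to 174 ± 14.3 CPM, lys-10 rose by 2.34 ± 0.25 and the invertebrate lysozyme ilys-2 by 2.61 ± 0.28. The more abundant lys-1 (626 ± 5.55 CPM in WT and 416 ± 64.6 in ced-3, adjusted p = 0.083) and lys-2 (279 ± 50.7 and 93.8 ± 37.2 CPM, adjusted p = 0.084), named here after their values were seen, passed only when adjusted over their list alone, as lower. In the other direction, the ABC transporter pgp-6 (WBGene00004000, chromosome X, 10871201 to 10877425) went from 389 ± 2.32 to 11.3 ± 0.982 CPM, a log2 fold of -5.10 ± 0.35 (adjusted p = 0.033). The glucuronosyltransferases ugt-26 and ugt-31, which conjugate small lipophilic compounds, fell by 2.82 ± 0.24 and fell by 2.99 ± 0.34 on the log2 scale, and the intestinal intermediate filament gene ifb-2 fell by 1.6 ± 0.16.

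In all, 240 of 13536 genes passed the test in ced-3 against WT, 190 higher and 50 lower. Of 17 furrow and other named collagens, 6 rose and none fell (14 rose when adjusted over the list alone). Named collagens had a median of 3.73 (camera adjusted p = 6.2e-10, adjusted p = 0.62 with an estimated correlation). Of 33 moulting cycle genes, 7 rose (18 adjusted over the list alone). Moulting cycle genes had a median of 1.77 (camera adjusted p = 2e-07, adjusted p = 0.62 with an estimated correlation). Of 87 genes of the col family 5 rose (32 adjusted over the list alone). Genes of the col family had a median of 0.93 (camera adjusted p = 1.1e-05, adjusted p = 0.62 with an estimated correlation). Of 25 lysozymes and other antimicrobial genes, 8 rose (10 rose and 2 fell when adjusted over the list alone). Lysozymes and other antimicrobial genes had a median of 0.55 (camera adjusted p = 0.0014, adjusted p = 0.62 with an estimated correlation). Among 18 immune effectors known to need PMK-1, 1 fell, T24B8.5, from 7.5 to 2.31 CPM (12 fell and 1 rose when adjusted over the list alone). Immune effectors had a median of -0.94 (camera adjusted p = 2.2e-05, adjusted p = 0.62 with an estimated correlation). Of 61 glucuronosyltransferase genes, 1 rose and 5 fell (6 and 11 adjusted over the list alone). Glucuronosyltransferase genes had a median of -0.29 (camera adjusted p = 0.026, adjusted p = 0.62 with an estimated correlation). Among 40 lipid genes 2 fell, the elongase elo-6 (520 ± 37.8 to 255 ± 10.7 CPM) and the acyltransferase dgat-2 (1 rose and 6 fell when adjusted over the list alone). Lipid genes had a median of -0.21 (camera adjusted p = 0.008, adjusted p = 0.68 with an estimated correlation). Of the 12 mitochondrially encoded genes none passed over all genes and 10 fell when adjusted over the list alone. Mitochondrially encoded genes had a median of -0.45 (camera adjusted p = 6.4e-05, adjusted p = 0.62 with an estimated correlation). Camera called 17 of 34 lists, 8 higher and 9 lower, and with an estimated correlation it called 0. Fry called 2 of the 17, the named collagens and the hypodermis and seam markers.

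Without WT replicate 1 or without WT replicate 2 edgeR called 0 genes, although all 240 kept the sign of their fold in both fits. DESeq2 on all libraries called 1337 genes and 3183 genes had an unadjusted p below 0.05. The edgeR count was 98 without ced-3 replicate 2 and 1479 without ced-3 replicate 1. Without ced-3 replicate 2, camera no longer called the lipid genes (adjusted p = 0.16) or the glucuronosyltransferases (adjusted p = 0.068).

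The comparison of pmk-1 with WT in mRNA asked which transcripts depend on the kinase. Several infection response genes were lower in pmk-1 worms. C17H12.8 (WBGene00015933, chromosome IV, 6818703 to 6820575) went from 64.1 ± 17.2 to 0.809 ± 0.188 CPM, a log2 fold of -6.28 ± 0.29 (adjusted p = 0.0061). The gene irg-5 (WBGene00009429, chromosome V, 13737010 to 13738474) went from 22.4 ± 0.193 to 0.995 ± 0.408 CPM, a log2 fold of -4.50 ± 0.27. The lysozymes lys-2 (279 ± 50.7 to 6.65 ± 2.24 CPM) and lys-1 (626 ± 5.55 to 151 ± 3.28 CPM) fell, the C-type lectin clec-67 fell from 51.8 to 0.253 CPM, and the glutathione S-transferase gst-13 fell by 2.15 ± 0.17 on the log2 scale. By edgeR 4 genes rose: the acyl-CoA synthetase acs-3 by 1.85 ± 0.21, H19N07.3 by 2.32 ± 0.24, the nuclear receptor gene nhr-235 by 1.6 ± 0.19 and the lysozyme lys-4 by 1.00 ± 0.12.

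In this comparison 57 of 13536 genes passed the test, 4 higher and 53 lower. Of the 18 immune effectors, 11 fell (14 fell and 1 rose when adjusted over the list alone). Immune effectors had a median of -4.38, also with dod-22, which had 0 counts in pmk-1 mRNA, at its bound (camera adjusted p = 2.7e-23, adjusted p = 0.5 with an estimated correlation). Of 25 lysozymes and other antimicrobial genes, 1 rose and 2 fell (5 and 5 adjusted over the list alone). Lysozymes and other antimicrobial genes had a median of -0.35 (camera adjusted p = 0.22). Of 98 C-type lectin genes 6 fell (5 rose and 12 fell when adjusted over the list alone). Lectin genes had a median of 0.10 and a mean of -0.16, with clec-21, which had 0 counts in pmk-1 mRNA, at its bound, and camera gave the list as lower with an adjusted p of 0.73. None of the 16 epidermal antimicrobial peptide genes passed over all genes (1 rose and 6 fell when adjusted over the list alone). Epidermal antimicrobial peptide genes had a median of -0.59 (camera adjusted p = 0.0011, adjusted p = 0.72 with an estimated correlation). Nor did any of the 33 moulting cycle genes (4 rose when adjusted over the list alone). Moulting cycle genes had a median of 0.72 (camera adjusted p = 0.00035, adjusted p = 0.92 with an estimated correlation). Some members differed widely between the pmk-1 replicates, such as fbn-1 (829 ± 697 CPM) and wrt-10 (121 ± 118 CPM). The col family had a median of -0.48 with no member past either adjustment (camera adjusted p = 0.025, adjusted p = 0.92 with an estimated correlation). Without pmk-1 replicate 1 camera turned the direction of this list (adjusted p = 0.64), and without WT replicate 2 its adjusted p was 0.2. Of the 17 named collagens none passed over all genes and 5 rose when adjusted over the list alone. The median of the named collagens was 0.28, and camera gave them as higher (adjusted p = 0.036, adjusted p = 0.92 with an estimated correlation; 0.28 without WT replicate 2). The 33 translation factors, with no member past either adjustment, had a median of 0.12 (camera adjusted p = 0.025, adjusted p = 0.92 with an estimated correlation). Their adjusted p was 0.092 without WT replicate 1, 0.098 without WT replicate 2 and 0.33 without pmk-1 replicate 1. Body wall muscle genes (20 tested, none past either adjustment) had a median of 0.18 (camera adjusted p = 0.045, adjusted p = 0.92 with an estimated correlation). Without WT replicate 1 and without pmk-1 replicate 1 that list had an adjusted p of 0.47 and 0.28. Of the 7 lists that camera called, fry called the immune effectors alone (adjusted p = 0.012).

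Without WT replicate 1 or without WT replicate 2, 2 genes passed, and without pmk-1 replicate 2 there were 388. DESeq2 called 377 genes, 165 higher and 212 lower. The 57 genes kept the sign of their fold under every leave-out of a library. C17H12.8 was the only named gene past the threshold under each of the leave-outs of a WT library, and camera kept the immune effectors under every leave-out.

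**Figure D2:**
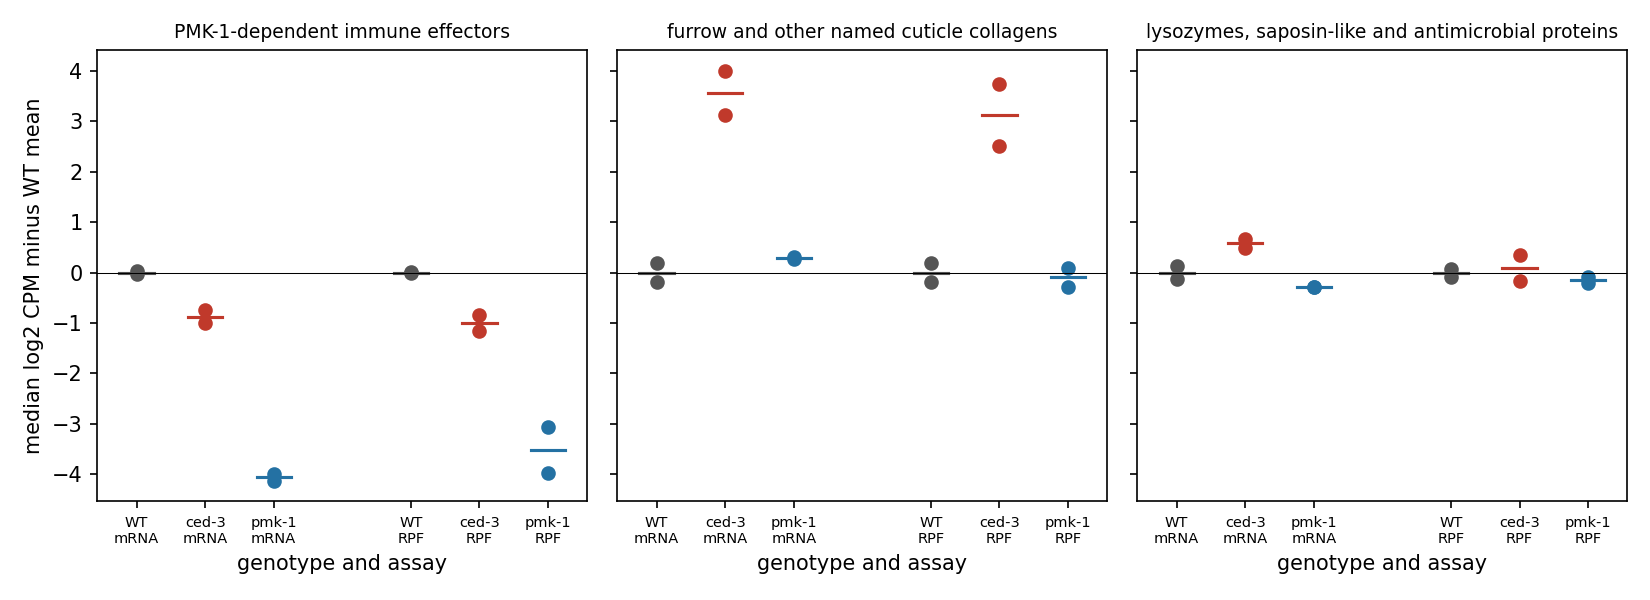
Points are libraries and dashes the mean of 2; the x axis gives genotype and assay, and the y axis the median over the genes of a list of log2 CPM minus the WT mean, for the immune effectors, the furrow and other named collagens, and the lysozymes and other antimicrobial genes. The immune effectors lie at -4 and -4.13 in pmk-1 mRNA and at -0.75 and -1.01 in ced-3 mRNA, while the named collagens lie at 3.13 and 4.01 in ced-3 mRNA and at 0.27 and 0.31 in pmk-1 mRNA.

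Setting the mutants directly against each other in mRNA gave more calls than either mutant against WT: 1247 genes, 909 higher in ced-3 and 338 higher in pmk-1. The fit held all 3 genotypes, so the WT libraries, which are not compared here, also set its spread. Replicates differed by more than 2-fold for 371 genes in WT, against 1135 in ced-3 and 1128 in pmk-1. A fit of the mutants alone called 0 genes. Several immune genes were higher in ced-3 than in pmk-1, dod-24 by 5.73 ± 0.34 and C17H12.8 by 5.43 ± 0.29 on the log2 scale. The lysozymes lys-7 (174 against 16.7 CPM) and lys-10 were higher by 3.37 ± 0.23 and 4.63 ± 0.29. The collagen sqt-1 was higher in ced-3 by 3.73 ± 0.37. The fatty acid elongases elo-6 and elo-5 were lower in ced-3 by log2 folds of -1.28 ± 0.11 and -1.26 ± 0.18, as were the mitochondrial chaperones hsp-6 (-0.89 ± 0.19) and hsp-60 (-0.77 ± 0.14) and the initiation factor eif-3.C (-0.59 ± 0.11). The fibrillin-related gene fbn-1 had 829 ± 697 CPM in pmk-1 and was lower in ced-3, by a log2 fold of -3.79 ± 0.68 that was -2.49 without pmk-1 replicate 1 and -4.46 without pmk-1 replicate 2.

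Of the 18 immune effectors 12 were higher and 1 lower in ced-3, with the same counts adjusted over the list alone. Immune effectors had a median of 3.48, also with dod-22 at its bound (camera adjusted p = 1.2e-07, adjusted p = 0.62 with an estimated correlation). Of 25 lysozymes and other antimicrobial genes 12 were higher and 1 lower (13 and 1 adjusted over the list alone). Lysozymes and other antimicrobial genes had a median of 1.21 (camera adjusted p = 5e-05, adjusted p = 0.62 with an estimated correlation). Of 17 named collagens 9 were higher (10 adjusted over the list alone). Named collagens had a median of 3.31 (camera adjusted p = 0.00031, adjusted p = 0.62 with an estimated correlation). Of 87 col genes 23 were higher and 2 lower (37 and 3 adjusted over the list alone). Genes of the col family had a median of 1.47 (camera adjusted p = 1.3e-06, adjusted p = 0.62 with an estimated correlation). Of 33 translation factors 4 were lower (20 adjusted over the list alone). Translation factors had a median of -0.35 (camera adjusted p = 1e-07, adjusted p = 0.62 with an estimated correlation). Among 18 genes of the mitochondrial unfolded protein response, 1 was higher and 4 lower (1 and 12 adjusted over the list alone). Genes of this mitochondrial response had a median of -0.42 (camera adjusted p = 0.00058, adjusted p = 0.62 with an estimated correlation). Of 40 lipid genes 2 were higher and 11 lower (4 and 14 adjusted over the list alone). Lipid genes had a median of -0.22 (camera adjusted p = 0.018, adjusted p = 0.69 with an estimated correlation). Of 33 cell cycle genes 5 were higher (11 adjusted over the list alone). Cell cycle genes had a median of 0.39 (camera adjusted p = 0.0027, adjusted p = 0.62 with an estimated correlation). Of the 16 lists called by camera, fry called 5: immune effectors, lysozymes, DAF-16 targets, named collagens and translation factors. Without pmk-1 replicate 1 the count was 64, without ced-3 replicate 2 it was 377, and in a fit of these groups alone edgeR called 0. DESeq2 called 2079 genes, and 4035 genes had an unadjusted p below 0.05. Camera no longer called the named collagens without pmk-1 replicate 2 (adjusted p = 0.095) or the lipid genes without ced-3 replicate 2 (adjusted p = 0.12).

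Across 13536 genes, the mRNA folds of ced-3 and pmk-1 against WT correlated at 0.17. Unchanged groups simulated against the same WT libraries gave 0.50 ± 0.011 (SD), and the covariance was 0.099 against a simulated 0.070, a difference of 0.029. With 1 WT library for each mutant, so that none was shared, the correlation was 0.2 (covariance 0.123) with WT replicate 1 for ced-3 and 0.01 (covariance 0.008) with WT replicate 2 for ced-3. Part of the overlap may come from the shared WT libraries. Called in both mutants were 11 genes, all in the same direction: acs-3, H19N07.3 and lys-4 were higher in both, and K11H12.4, pgp-6, oac-20, ugt-26, T24B8.5, the folate transporter family gene folt-2, F55G11.8 and the peptidase pcp-2 were lower in both. Of these, F55G11.8 and pcp-2 were named after their values were seen. Simulated unchanged groups shared 0.14 such genes, which leaves out the effects, and independent lists would share 0.06 higher and 0.20 lower, which leaves out the shared WT libraries. With the controls split, edgeR called 0 genes in both, and DESeq2 called 11 and 7 higher in both and 9 and 8 lower in both, in the order above, with 2 genes in opposite directions each way. In RPF the correlation was 0.16 (simulated 0.51 ± 0.01), and 0 genes passed in both by edgeR, where 3000 genes had an unadjusted p below 0.05 in ced-3 and 1097 in pmk-1. The mRNA correlation was 0.34 without WT replicate 1, 0.28 without WT replicate 2 and 0.04 without pmk-1 replicate 2; in RPF it was 0.33, 0.32 and 0.02. With the WT libraries split the RPF correlation was 0.18 with WT replicate 1 for ced-3 and -0.01 with WT replicate 2 for ced-3.

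In RPF, the comparison of ced-3 with WT asked which messages differ on ribosomes without the caspase. The RPF of wrt-2 went from 2.57 to 53.0 ± 13.8 CPM (log2 4.38 ± 0.34, adjusted p = 0.031), and pitr-5, C28C12.4 and F10C1.8 rose by 3.80 ± 0.29, 2.92 ± 0.21 and 2.60 ± 0.23. The RPF of pgp-6 went from 318 ± 4.53 to 4.38 ± 1.14 CPM (log2 -6.19 ± 0.45, adjusted p = 0.035), and those of ugt-26 from 381 to 50.4 CPM. C07A9.12 (WBGene00043994, chromosome III, 9725281 to 9727539) had 16 CPM in WT, 18 in pmk-1 and 0 counts in ced-3, at least 89.4-fold lower than WT against a floor of 3 counts over both ced-3 libraries; its mRNA in ced-3 was 0.237 ± 0.0824 CPM against 9.35 ± 0.442 in WT.

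These 7 genes, 4 higher and 3 lower, were all that passed among 12633. None of the 17 named collagens passed over all genes and 13 rose when adjusted over the list alone. Named collagens had a median of 3.46 (camera adjusted p = 2e-08, adjusted p = 0.54 with an estimated correlation). Of 33 moulting cycle genes 1 rose (15 adjusted over the list alone). Moulting cycle genes had a median of 1.75 (camera adjusted p = 3.7e-07, adjusted p = 0.54 with an estimated correlation). No immune effector of 19 passed over all genes and 5 fell when adjusted over the list alone. Immune effectors had a median of -1.22 (camera adjusted p = 6.2e-06, adjusted p = 0.54 with an estimated correlation). Ribosomal proteins had a median of -0.47 (camera adjusted p = 1e-07, adjusted p = 0.72 with an estimated correlation, and 0.26 at the preset correlation without ced-3 replicate 1). Translation factors had a median of -0.41 (camera adjusted p = 2.8e-06, adjusted p = 0.56 with an estimated correlation). No member of these 2 lists passed either adjustment. Of 20 intestinal genes 1 rose and 9 fell when adjusted over the list alone and none over all genes. Intestinal genes had a median of -0.66 (camera adjusted p = 0.00038, adjusted p = 0.54 with an estimated correlation). Camera called 13 lists, and fry called 4 of them, among these the named collagens and intestinal genes but not the moulting cycle genes or immune effectors. The count of 7 was 0 without WT replicate 1 or without WT replicate 2, 1249 without ced-3 replicate 1 and 142 without ced-3 replicate 2. DESeq2 called 1314, edgeR without its robust option 327, and 3000 genes had an unadjusted p below 0.05.

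In pmk-1 against WT, RPF of several infection response genes were lower. Those of irg-4 went from 423 ± 24.5 to 32.1 ± 0.273 CPM (log2 -3.72 ± 0.23, adjusted p = 0.0088), those of irg-5 from 41.9 to 2.28 CPM, and those of T24B8.5 from 18.8 to 1.29 CPM. The sulfatase family gene sul-3 (-5.08 ± 0.32), lys-1 (-1.84 ± 0.17) and lys-10 (-2.25 ± 0.25) were lower too. The RPF of acs-3 and R11D1.3 rose, by 2.18 ± 0.21 and 2.04 ± 0.22. In all 23 of 12633 genes passed, 2 higher and 21 lower. Of 19 immune effectors 5 fell (15 fell and 1 rose when adjusted over the list alone). Immune effectors had a median of -3.72 (camera adjusted p = 6e-22, adjusted p = 0.82 with an estimated correlation), and their median log2 CPM against the WT mean was -3.98 in replicate 1 and -3.06 in replicate 2. None of the 11 mitochondrially encoded genes passed over all genes and 9 fell when adjusted over the list alone. Mitochondrially encoded genes had a median of -1.93 (camera adjusted p = 1.7e-09, adjusted p = 0.82 with an estimated correlation). Among 15 epidermal antimicrobial peptide genes none passed over all genes and 3 fell when adjusted over the list alone. Epidermal antimicrobial peptide genes had a median of -0.65 (camera adjusted p = 0.00011, adjusted p = 0.82 with an estimated correlation). Camera called 7 lists, 1 higher and 6 lower, and fry called none of them (adjusted p = 0.081 for the immune effectors and 0.34 for the mitochondrially encoded genes). Moulting cycle genes (33 tested) were the higher one, with a median of 0.47 and no member past either adjustment (camera adjusted p = 3e-04, adjusted p = 0.96 with an estimated correlation). Some of them differed widely between the pmk-1 RPF replicates, such as fbn-1 (684 ± 573 CPM) and wrt-10 (222 ± 214 CPM). The col family (83 tested) had a median of -0.63 and no member past either adjustment (camera adjusted p = 7e-06, adjusted p = 0.96 with an estimated correlation; 0.24 without pmk-1 replicate 1). Histones (31 tested) had a median of -0.38, again with no member past either adjustment (camera adjusted p = 7e-05, adjusted p = 0.82 with an estimated correlation). Of 17 components of the p38 pathway none passed over all genes and 2 fell when adjusted over the list alone. The mutated gene pmk-1 itself was among these, as the member with the largest fall (-0.98 ± 0.15), and the list was not tested without it. Genes of the p38 pathway had a median of -0.29 (camera adjusted p = 0.0023, adjusted p = 0.91 with an estimated correlation; 0.13 without WT replicate 1). Without WT replicate 1, WT replicate 2 or pmk-1 replicate 1 edgeR called 0 genes, and without pmk-1 replicate 2 it called 205. DESeq2 called 281, and 1097 genes had an unadjusted p below 0.05.

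Between the mutants, RPF differed for 1088 genes, 764 higher in ced-3 and 324 higher in pmk-1, in the fit that also held WT. The lysozymes lys-10 and lys-7 were higher in ced-3 by 4.39 ± 0.25 and 2.92 ± 0.29, irg-5 by 3.44 ± 0.22, and the p38 phosphatase gene vhp-1 by 1.17 ± 0.22. The desaturase fat-3 and the elongases elo-6 and elo-1 were lower in ced-3, by log2 folds of -1.90 ± 0.21, -1.90 ± 0.21 and -1.39 ± 0.14 (adjusted p = 0.029 each), and so was the intestinal phosphatase pho-1 (-1.23 ± 0.17). Of 19 immune effectors 7 were higher and 1 lower (12 and 1 adjusted over the list alone). Immune effectors had a median of 2.49 (camera adjusted p = 2.4e-05, adjusted p = 0.48 with an estimated correlation). Of 40 lipid genes 1 was higher and 11 lower (3 and 12 adjusted over the list alone). Lipid genes had a median of -0.43 (camera adjusted p = 0.0048, adjusted p = 0.48 with an estimated correlation). Of 58 glucuronosyltransferase genes 2 were higher and 11 lower (5 and 24 adjusted over the list alone). Glucuronosyltransferase genes had a median of -0.50 (camera adjusted p = 0.0039, adjusted p = 0.48 with an estimated correlation). Of 20 intestinal genes 5 were lower (1 higher and 8 lower when adjusted over the list alone). Intestinal genes had a median of -0.42 (camera adjusted p = 0.0039, adjusted p = 0.48 with an estimated correlation). By fry 10 of the 16 lists called by camera passed, with these 4 among them. Without pmk-1 replicate 1 edgeR called 0, as in a fit of these groups alone, without pmk-1 replicate 2 it called 692 and without ced-3 replicate 2 it called 636. DESeq2 called 1916, and 3764 genes had an unadjusted p below 0.05.

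RPF followed mRNA across genes in both mutants. Over 12468 genes tested in both assays, the folds correlated at 0.92 in ced-3, with a slope of RPF on mRNA of 1.02, and at 0.82 in pmk-1, with a slope of 0.85. Without a filter on low counts these correlations were 0.47 and 0.30. All 233 genes called in ced-3 mRNA and tested in RPF had the same sign in RPF, as did all 56 of pmk-1; 7 genes in ced-3 and 20 in pmk-1 were called in both assays. The RPF and mRNA libraries of a replicate came from the same worms, so these values share the spread between worm samples.

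The TE comparisons asked whether ribosome occupancy changed beyond mRNA. For ced-3 against WT, edgeR called 0 of 13698 genes, with 221 at an unadjusted p below 0.05 and 1 call by DESeq2. With worm samples paired it called 3, 1 higher and 2 lower, with 679 at an unadjusted p below 0.05, and 68 without ced-3 replicate 2 and 1 without ced-3 replicate 1. For pmk-1 it called 0, with 172 at an unadjusted p below 0.05 and 5 calls by DESeq2. With worm samples paired, the same test called 2, 1 higher and 1 lower, with 460 at an unadjusted p below 0.05, and 1 without WT replicate 1, WT replicate 2 or pmk-1 replicate 1. Camera called the TE of 6 lists lower in ced-3, with no member past the threshold over all genes. Fry called no list (lowest adjusted p 0.63, and 0.087 with worm samples paired, where camera called 7). The 80 ribosomal proteins had a median of -0.26 (camera adjusted p = 4.5e-12, adjusted p = 0.72 with an estimated correlation), the 25 lysozymes and other antimicrobial genes one of -0.29 (camera adjusted p = 4.8e-05, adjusted p = 0.52 with an estimated correlation) and the 20 intestinal genes one of -0.25 (camera adjusted p = 1.1e-06, adjusted p = 0.15 with an estimated correlation). Adjusted over the list alone, 2 of the intestinal genes fell, and none of the ribosomal proteins or lysozymes passed. Without ced-3 replicate 1 the direction of the ribosomal proteins turned (adjusted p = 2.4e-05), and without WT replicate 2 the adjusted p was 0.11 for the ribosomal proteins and 0.31 for the lysozymes.

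Camera called 4 lists in TE of pmk-1, and 8 with worm samples paired, and fry called no list in either (lowest adjusted p 0.99 and 0.56). The TE of the 12 mitochondrially encoded genes was lower, with a median of -1.75 (camera adjusted p = 1.5e-17, adjusted p = 0.47 with an estimated correlation). None passed over all genes and 9 fell when adjusted over the list alone. With worm samples paired, 1 of them passed over all genes, nduo-2, a subunit of NADH dehydrogenase (log2 -2.15 ± 0.32, adjusted p = 0.044). Its RPF were 4.2 ± 0.799 CPM in WT and 0.777 ± 0.18 in pmk-1, against mRNA of 583 ± 9.69 and 483 ± 20.1 CPM. Its TE fold thus rests on few RPF reads. The mitochondrially encoded genes are translated inside mitochondria, and their RPF libraries differed within groups: their median log2 CPM against the WT mean was -0.37 and 0.37 in WT, 0.21 and -1.08 in ced-3, and -2.14 and -1.54 in pmk-1. The 32 histone genes tested had a median of -0.29 (none past either adjustment, camera adjusted p = 8.3e-08, adjusted p = 0.47 with an estimated correlation), which was lost without WT replicate 1 (adjusted p = 0.84). For pmk-1 itself the TE in pmk-1 worms was -0.94 ± 0.16 (adjusted p = 1 by edgeR, 0.058 with worm samples paired and 0.045 by DESeq2). Counts per gene do not show whether the lost RPF lay over the part of pmk-1 that the allele changes. This fold therefore need not be a change in how the message is translated.

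The cation-transporting ATPase gene catp-3 was called higher in TE in pmk-1 with worm samples paired (log2 3.12 ± 0.26, adjusted p = 3.8e-05), while its mRNA fell from 263 to 0.887 ± 1.16 CPM and its RPF had a log2 fold of -5.04 ± 1.47 in pmk-1 against WT (adjusted p = 0.44). The RPF of pmk-1 replicate 2 held 6% of the WT level of catp-3 and those of replicate 1 held 0.0287%, and without pmk-1 replicate 2 the paired fit called 0 genes in TE by edgeR, against 5 by DESeq2 on all libraries without pairing. In mRNA its log2 fold was -8.14 ± 0.80 with all libraries, -7.26 without pmk-1 replicate 1 and -11.77 without pmk-1 replicate 2.

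**Figure D3:**
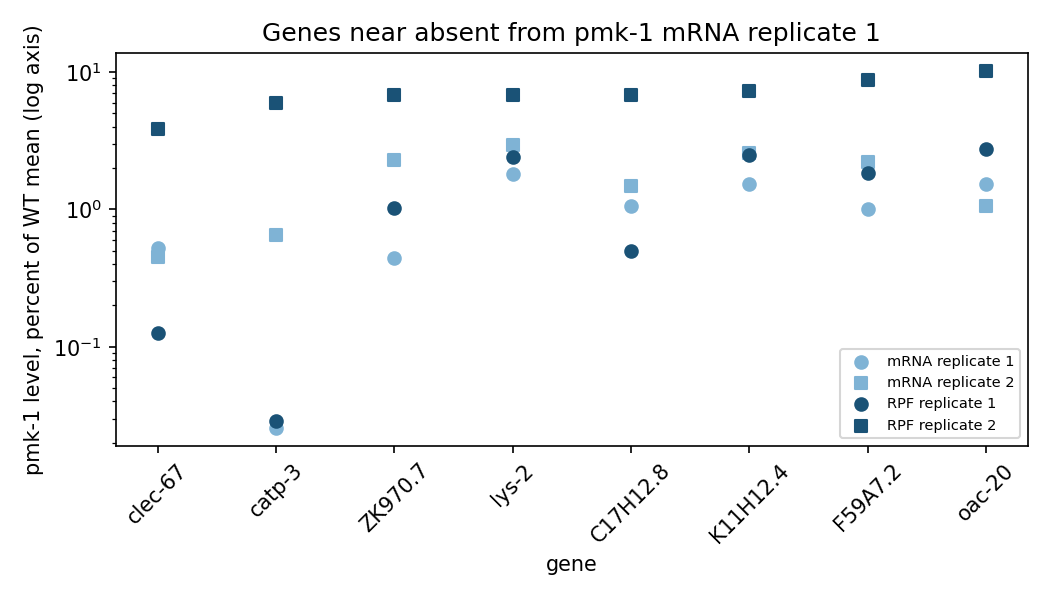
The y axis (log scale) gives the level in each pmk-1 library as percent of the WT mean of the same assay, for 8 genes (x axis) with less than 2% of the WT level in pmk-1 mRNA replicate 1 and at least 20 CPM in WT RPF, chosen after their values were seen. Pale points are mRNA, dark points RPF, circles replicate 1 and squares replicate 2; RPF replicate 2 lies between 3.87% and 10.2% for these genes.

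The comparison of RPF with mRNA in WT asked which messages were on ribosomes more or less than their abundance. The messages of glycolytic enzymes were higher in RPF: the aldolase aldo-1 by 1.2 ± 0.18 on the log2 scale (adjusted p = 0.00099) and the kinase pgk-1 by 0.77 ± 0.11. The peroxiredoxin prdx-2 (1.38 ± 0.15) and the C-type lectin clec-83 (2.54 ± 0.16) were higher as well. Mitochondrially encoded messages were lower, nduo-2 by a log2 fold of -7.32 ± 0.30, as were ribosomal protein messages such as rps-2 (-1.47 ± 0.18), the synaptic vesicle priming gene unc-13 (-2.48 ± 0.15) and the nuclear receptor gene nhr-97 (-3.41 ± 0.20). Of 17 genes of the p38 pathway 2 were higher and 5 lower, the kinases pmk-2 (-2.17 ± 0.22) and sek-1 (-1.19 ± 0.15) among the lower. Camera did not call this list (adjusted p = 0.42). In all 4552 of 13698 genes differed, 1866 higher and 2686 lower, and 7177 with worm samples paired, 3523 higher and 3654 lower.

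Of 21 glycolysis genes 13 were higher in RPF (14 adjusted over the list alone). Glycolysis genes had a median of 0.53 (camera adjusted p = 1.6e-05, adjusted p = 0.67 with an estimated correlation). Of 28 oxidative stress genes 11 were higher and 1 lower (11 and 2 adjusted over the list alone). Oxidative stress genes had a median of 0.57 (camera adjusted p = 0.0049, adjusted p = 0.67 with an estimated correlation). Of 80 ribosomal proteins 1 was higher and 57 lower (1 and 62 adjusted over the list alone). Ribosomal proteins had a median of -1.01 (camera adjusted p = 5.3e-11, adjusted p = 0.77 with an estimated correlation). All 12 mitochondrially encoded genes were lower by both adjustments. Mitochondrially encoded genes had a median of -7.28 (camera adjusted p = 2.2e-12, adjusted p = 0.67 with an estimated correlation). Of 204 nuclear receptor genes 7 were higher and 53 lower (7 and 50 adjusted over the list alone). Nuclear receptor genes had a median of -0.47 (camera adjusted p = 0.00029, adjusted p = 0.67 with an estimated correlation). Fry called 7 of the 8 lists that camera called, with these 5 among them. Without WT replicate 1 the count of genes was 1532 and without WT replicate 2 it was 1656. The assays also differ in how the libraries were made, so a difference here compares the libraries as well as ribosome occupancy.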

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

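Chosen after the results were seen were both tests in this part and the paired TE fits taken as results of their own. With worm samples paired, the effect of a mutation on RPF differed from its effect on mRNA for 5 genes, by edgeR's test of the interaction of genotype and assay. In ced-3, the cathepsin B-like protease gene cpr-1 had a TE fold of -1.15 ± 0.16 on the log2 scale (adjusted p = 0.034), with mRNA of 324 CPM in WT and 471 in ced-3 and RPF of 467 and 293. For C23H3.9 the TE fold in ced-3 was 1.56 ± 0.23 (adjusted p = 0.034), and for C32F10.4 it was -1.36 ± 0.21 (adjusted p = 0.034). These genes and catp-3 in TE were named after their values were seen. In pmk-1, nduo-2 had a TE fold of -2.15 ± 0.32 (adjusted p = 0.044) and catp-3 one of 3.12 ± 0.26 (adjusted p = 3.8e-05). The fold of nduo-2 rests on RPF of 4.2 ± 0.799 CPM in WT and 0.777 ± 0.18 CPM in pmk-1. The count of 3 for ced-3 was 1 without ced-3 replicate 1 and 68 without ced-3 replicate 2, and the count of 2 for pmk-1 was 1 without WT replicate 1, WT replicate 2 or pmk-1 replicate 1 and 0 without pmk-1 replicate 2.

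The value of catp-3 belongs to a wider pattern: 8 genes chosen on pmk-1 mRNA replicate 1 and the WT level in RPF (lys-2, oac-20, ZK970.7, catp-3, C17H12.8, clec-67, F59A7.2 and K11H12.4) were near absent from pmk-1 mRNA replicate 1, yet kept a median of 6.84% of the WT level in pmk-1 RPF replicate 2, against 1.44% in RPF replicate 1, 1.84% in mRNA replicate 2 and 1.03% in mRNA replicate 1. Other worms in that sample before it was split would leave a like share in mRNA and RPF, and the tables argue against this, since the share in RPF replicate 2 was 3.73 times that in mRNA replicate 2. Reads of another library in pmk-1 RPF replicate 2 remain a candidate explanation: the shares of the WT level had an SD of 0.41 on the log2 scale over the 8 genes, and those of the ced-3 level an SD of 0.94. The genes were chosen as low in mRNA replicate 1, from the same worms as RPF replicate 1, so its low share was partly selected. Outside the 8 genes the picture was mixed. The RPF of irg-4 and clec-66 were 32.1 ± 0.273 and 22.8 ± 0.0442 CPM in pmk-1, so the replicates hardly differed. The log2 folds of dod-24 and K08D8.4 went from -4.06 and -3.56 to -4.72 and -4.26 without pmk-1 replicate 2. The RPF of sul-3, the largest fall named in RPF of pmk-1, were 0.568 ± 0.191 CPM in pmk-1 against 19.9 ± 3.35 in WT. Both pmk-1 replicates thus held less of its WT level than the median of 6.84%. Mixing of worms or lysate after the split and mixing of reads in sequencing were not separated, and no biological explanation was tested. If reads of another library were present, the TE fold of catp-3 may come from 1 library. Some RPF falls in pmk-1 of genes near absent from its mRNA may then be larger than reported.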

How the results depend on the processing

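Leaving out ced-3 replicate 2 and pmk-1 replicate 1 together, splitting the WT libraries between the mutants, and the paired TE fits as results of their own, were chosen after seeing the data. With RLE factors the counts of genes called stayed within 1.5 times for all 9 comparisons without pairing (166, 56, 1239, 7, 23, 1077, 0, 0 and 4577, in the order of the report). Over the single genes named and all alternatives, 5607 values kept their direction and their side of the threshold, 1131 lost the call, 270 gained it and 26 changed sign. At 2 libraries per group, the simulations recovered few changes of 2-fold. Unless the alternative itself removed samples or genes, the cause was not tested.

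DESeq2 called 1337 genes in mRNA for ced-3 against WT (948 higher, 389 lower), 377 for pmk-1 against WT (165 and 212) and 2079 for ced-3 against pmk-1; in RPF it called 1314, 281 and 1916, and in TE 1 for ced-3 and 5 for pmk-1. Without a filter, edgeR called 827 and 221 genes in mRNA for ced-3 and pmk-1 against WT, 1012, 212 and 1713 in RPF, and 2 in TE of pmk-1; the lists called numbered 3 in pmk-1 mRNA, 3 in TE of ced-3 and 14 for RPF against mRNA; the correlation of folds was 0.41 between the mutants in mRNA and 0.39 in RPF, and 0.47 between mRNA and RPF in ced-3 and 0.30 in pmk-1. Without the robust option edgeR called 403 genes in ced-3 mRNA and 327 in ced-3 RPF. In RPF it called 185 for ced-3 among protein coding genes. Fits of the compared groups alone called 198 genes in RPF of ced-3, 47 in RPF of pmk-1, and 0 between the mutants in mRNA and in RPF. With an estimated correlation camera called 0 lists in all 9 comparisons.

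The replicate numbers do not pair the genotypes: deviations from the group means of same-numbered libraries correlated at -0.01, -0.10 and 0.11 in mRNA and 0.01, -0.10 and 0.10 in RPF. With the replicate block edgeR called 0 (ced-3), 27 (pmk-1) and 564 (ced-3 against pmk-1) genes in mRNA and 0, 0 and 496 in RPF. For TE and RPF against mRNA, where the block is the worm sample, it called 3, 2 and 7177 genes, and 8 lists in TE of pmk-1; it moved no other count of lists by more than 1.5 times. With worm samples paired, TE of ced-3 and pmk-1 had 6 (1 higher, 5 lower) and 5 (1 and 4) calls with RLE factors, 49 and 43 without a filter, and 8 and 1 among protein coding genes.

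Leaving out 1 library at a time gave 0 to 1479 genes in mRNA for ced-3 against WT, 2 to 388 for pmk-1 against WT and 64 to 1821 for ced-3 against pmk-1. In RPF the ranges were 0 to 1249, 0 to 205 and 0 to 1548; in TE of pmk-1 0 to 1, with worm samples paired 1 to 68 (ced-3) and 0 to 1 (pmk-1), and for RPF against mRNA 1532 to 1656. Lists called ranged from 4 to 11 in pmk-1 mRNA, 6 to 11 in pmk-1 RPF, 2 to 8 in TE of ced-3 and 1 to 7 in TE of pmk-1. Correlations of folds ranged from 0.04 to 0.34 between the mutants in mRNA, 0.02 to 0.33 in RPF, and from 0.80 to 0.91 (ced-3) and 0.62 to 0.80 (pmk-1) between mRNA and RPF. Without ced-3 replicate 2 and pmk-1 replicate 1 together, the calls against WT were 1372 (ced-3) and 348 (pmk-1) in mRNA and 1264 and 241 in RPF, and mRNA and RPF folds correlated at 0.81 and 0.68.

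Genes whose log2 fold changed sign had not passed the test. The fold of ced-3 in TE of pmk-1 was 0.01, and it was 0 with RLE factors, -0.01 with DESeq2, -0.02 without a filter, -0.02 with the replicate block and -0.34 to 0.32 over the leave-outs. Over the leave-outs, ced-3 ranged from -1.05 to 0.09 in mRNA of pmk-1 and from -0.36 to 0.54 in RPF of ced-3. The vitellogenin gene vit-1 ranged from -1.95 to 0.46 in mRNA of pmk-1, -0.26 to 1.11 in mRNA of ced-3, -0.01 to 2.45 between the mutants, -1.33 to 0.68 in TE of pmk-1 and -0.97 to 0.60 for RPF against mRNA. In TE, his-8 ranged from -2.1 to 0.44 and nduo-2 from -0.57 to 0.08 in ced-3, and nhr-85 from -0.45 to 0.06 in pmk-1; lin-29 ranged from -0.15 to 1.00 in mRNA of pmk-1. Without the libraries farthest apart, vit-1 had -0.27 (ced-3), 0.46 (pmk-1) and -0.73 (ced-3 against pmk-1), and lin-29 had -0.15 in pmk-1.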

Other observations

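Of the tests in this part, the ones on the immune effectors and on linkage were written down before their results were seen; the tests on larval timing, on scaling factors and on shared WT libraries were chosen after. Beyond the lists described above, camera called several others in ced-3 mRNA. Histone genes (33 tested, median 0.43, camera adjusted p = 6.4e-05, adjusted p = 0.62 with an estimated correlation) and cell cycle genes (33 tested, median 0.38, camera adjusted p = 0.0023, adjusted p = 0.62 with an estimated correlation) were higher as sets with no member past either adjustment. DAF-16 targets (22 tested, median 0.26, camera adjusted p = 0.033, adjusted p = 0.62 with an estimated correlation) had 3 members that rose, which were dod-3, lys-7 and the glyoxylate cycle gene icl-1 (1.1 ± 0.14); adjusted over the list alone 5 rose and 1 fell, and without ced-3 replicate 1 the list had an adjusted p of 0.23. Translation factors (33 tested, median -0.26, camera adjusted p = 7.5e-06, adjusted p = 0.62 with an estimated correlation) and glycolysis genes (21 tested, median -0.35, camera adjusted p = 0.0024, adjusted p = 0.62 with an estimated correlation) were lower as sets, with no member past either adjustment. The mitochondrial unfolded protein response (18 tested, median -0.30, camera adjusted p = 0.00021, adjusted p = 0.62 with an estimated correlation) had none past the threshold over all genes, and 1 rose and 7 fell when adjusted over the list alone.

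Between ced-3 and WT in mRNA, marker lists for body wall muscle (median -0.02, camera adjusted p = 0.46), pharynx (0.13, adjusted p = 0.92), neurons (0.09, adjusted p = 0.35), germline (0.02, adjusted p = 0.96) and intestine (-0.22, adjusted p = 0.13) were not called, although in the intestine list ifb-2 fell. Hypodermis and seam markers (17 tested) were called higher: 2 rose (4 adjusted over the list alone; median 0.33; camera adjusted p = 0.02, adjusted p = 0.62 with an estimated correlation), and the adjusted p was 0.052 without WT replicate 1 and 0.064 without ced-3 replicate 1. Between the mutants, 4 of 16 epidermal antimicrobial peptide genes were higher in ced-3 mRNA (8 adjusted over the list alone; median 0.89; camera adjusted p = 0.028, adjusted p = 0.62 with an estimated correlation; 0.52 without ced-3 replicate 1), and so was 1 hexokinase gene, hxk-1 (1.05 ± 0.12).

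The first principal component set ced-3 and pmk-1 on opposite sides of WT and also parted the replicates of each mutant. With the mean log2 CPM of each library taken out, which removes any scaling factor, the gap between the mean scores of the mutants on this component was 108.3 in mRNA against 110.6 with TMM factors (113 against 114.8 in RPF), which argues against scaling as its cause. If the component were the position of the worms in larval development or the moulting cycle, apart from genotype, the difference between the pmk-1 replicates could follow the difference of ced-3 from WT; across genes the correlation was 0.096 in mRNA, just under the bound of 0.1 set against this explanation, and 0.13 in RPF, just over it, so timing and genotype cannot be told apart here (that both assays must lie on 1 side was decided after the values were seen). Of the other pairs of differences that share no library, the ced-3 replicate difference (replicate 2 minus replicate 1) correlated with WT minus pmk-1 at -0.05 in mRNA and -0.03 in RPF, and the WT replicate difference with ced-3 minus pmk-1 at -0.27 in both assays. For the lower immune effectors in pmk-1, the difference between the ced-3 replicates followed the difference of pmk-1 from WT across genes with a slope of 0.05 and a correlation of 0.05. With the part that follows the difference between the ced-3 replicates removed, the median log2 CPM difference of the effectors from WT was -4.25 (SD 2.68 over 18 genes, 17 below 0), against -4.31 before. So little was removed that this decides nothing, and that axis and a direct effect of the mutation cannot be told apart by it (that so low a correlation leaves it undecided was set after the values were seen).

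The 8 genes lower in both mutants than in WT were weighed next. With 1 WT library for ced-3 and the other for pmk-1, so that none was shared, DESeq2 called 8 and 9 genes lower in both. Independent lists would share 0.42 and 0.37. By DESeq2 alone these counts argue against chance values of the shared WT libraries as the whole source. Among the genes called were 6 and 5 of the 8. These had been chosen with the same libraries, so their return is no further support. EdgeR, with 2 genes called in pmk-1 and 0 in ced-3, could not be used. The bound of at least 8 genes used here was set after the values were seen, and each split also gave 2 genes in opposite directions. A true difference of the WT cultures from both mutants remains possible. Alleles linked to the mutations, which lie on chromosome IV, may add to it: 3 of the 8 genes (pcp-2, F55G11.8 and K11H12.4) lie on that chromosome, which holds 15.9% of the genes tested, between the bounds set in advance of at least 4 and at most 1. Linkage, the WT cultures and a shared effect of both mutations therefore cannot be told apart for these genes.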
